A study of Mus musculus with 2 samples.

How the data were processed

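DNase-seq measures where chromatin is accessible: nuclei are treated with the endonuclease DNase I, which cuts exposed DNA, and the cut ends are sequenced. The libraries came from the hearts of 2 male mice aged 4 days, offspring of a cross of the C57BL/6J and CAST laboratory strains, and per the labels they were biological replicates 1 and 2 of 1 experiment with 1 library each. The labels number the males and the heart samples separately but give both the same donor identifier, so that the libraries stand for 2 animals is a reading of the labels. If they came from 1 animal, each SD with n = 2 would be a spread between samples of that animal. Both mice belong to 1 group, so no comparison between conditions was possible, and the comparisons made were between the replicates, between classes of genes and regions within the same hearts, and against random or shuffled controls. The spread between the 2 mice had a single degree of freedom and is given as mean ± SD with n = 2.

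For each mouse 4 files of the authors were used, all made from that mouse's own filtered alignments to mm10 per the deposited file listing, with no pooling of the replicates. The aligner, the peak and footprint callers and their versions are not given in the sources used here. The deposited peak lists carry a signal value per peak, called its height below, which is the authors' own score. Heights were whole multiples of a small step within each mouse, 0.00486 in replicate 1 and 0.00356 in replicate 2, for 100% of peaks within a tolerance of 0.05 steps. If 1 step stood for 1 cut after scaling every library to the same total, the depth of replicate 2 would be 1.36 times that of replicate 1, but the scaling is not stated, so means, ratios and correlations of heights across the mice take the authors' values as comparable between the libraries, which was not tested. The authors deposited 2 peak lists per mouse. In the shorter list, which was the main list here, every peak held a position with a deposited false discovery rate (a q-value for the local cut rate) of 0.001 or less, and in the longer list of 0.05 or less. The deposited file of these q-values listed 31120875 intervals in replicate 1 and 39432590 in replicate 2, all with a value of 0.05 or less. The deposited footprints, short stretches protected from cutting inside accessible DNA, all carried 1 constant value of 0.01, read as a q-value of the list, so they could not be ranked or filtered further.

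Coordinates are mm10, and the reference sequence used was GRCm38.p6 with the GENCODE M21 basic annotation, in which every peak lay within the chromosome ends. The annotation held 21851 protein-coding genes with 41438 transcription start sites (TSSs) on 21 chromosomes, and 77161 TSSs of any gene. Intervals were compared with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and plots were drawn with Matplotlib 3.10.9. Peaks or footprints of the mice were called shared when they overlapped by at least 1 bp, and the shares were set beside the mean of 100 random placements, starting outside assembly gaps of the same chromosome for peaks and within the shared regions for footprints. Merged regions holding a peak of both mice are called shared regions. Heights were correlated on a log2(height + 1) scale, with 0 where a mouse had no peak in either list, across regions, which are not independent replicates.

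A promoter was open when a peak lay within 1000 bp of any TSS of the gene in both mice, unless stated otherwise. The promoter height of a gene in a mouse is that of its tallest such peak. This peak can lie at a start inside the gene, and it need not be the same peak in both mice. Distal regions lay more than 1000 bp from every annotated TSS and were assigned to the gene with the nearest protein-coding TSS. The 28 gene lists and 27 consensus sequences, the tests, the rule for named genes and all alternatives except 3 added later were fixed before the data were examined. List genes were compared with all other protein-coding genes by Fisher's exact test, 2-sided, with Benjamini-Hochberg adjustment over the 28 lists. The median number of shared distal peaks per gene of a list was compared with 10000 random lists of the same size matched in 20 bins of territory, the length of DNA nearest to the gene's TSSs, by a 2-sided permutation test with the same adjustment. Every consensus was searched on both strands of the shared regions, and the share of sites whose centre lay in a footprint was compared, per mouse, with sites of 10 letter shuffles of the consensus by Fisher's exact test, adjusted over motifs and mice. A motif was called when both mice passed an adjusted p of 0.05 in the same direction. X-linked and autosomal promoters were compared by a permutation test across genes with 100000 resamples, 2-sided. These p-values describe genes and sites in these hearts, not animals, and neighbouring genes and overlapping sites are not independent. Intervals of shares are exact Clopper-Pearson 95% intervals and cover counting error only.

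On simulated data with the real 21851 genes and 28 lists, a 6-fold change in the odds of openness in 6 lists was called in 41% of those lists and 0.545% of unchanged lists were called. For distal peaks a 4-fold change of the mean in 6 lists was called in 83.3% and unchanged lists in 0%, over 3 simulations against 100 for promoters, so these shares are rough. All 99 consensus sites planted in a made-up sequence were found. Smaller differences in short lists would often be missed at these list sizes.

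The genes named were, from each list called for promoter openness, up to 2 with the strongest promoter peak by mean rank over the mice and up to 2 with no promoter peak in either mouse, taken in list order, and up to 1 of each kind from every other list. From each list called for distal peaks, the 3 genes with most shared distal peaks were added. The 10 genes with most distal peaks genome-wide, the genes of the 5 most peak-dense windows of 100 kb, and 15 genes of heart biology fixed in advance completed the rule. Not every gene the rule selects is named. Of the listed symbols 1, Ahsp, had no match in the annotation. Alternatives were other overlap, window, list and matching rules, the longer lists, the upper 50% of peaks by height and each mouse alone. The consensus of the neuronal silencer REST had no shuffled sites in the shared regions and was left out of the tests. Alleles of the 2 parental strains were not separated, and a loss of reads that differ from the reference strain was not tested. Whether reads from genes with near-identical copies were lost in the filtered alignments was not tested either. A gene without a peak therefore need not be closed.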

Results

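The hearts of 2 male mice, 4 days old, were profiled by DNase-seq, with 1 library per animal as the sample descriptions read, although both samples carry the same donor label. The labels state no hypothesis, and the design gives 1 group of 2 biological replicates. The comparisons therefore ask how far the accessible regions of the hearts overlapped, where in the genome they lay, which groups of genes carried them and which binding sequences were protected within them. Replicate 1 had 88222 peaks with a median width of 220 bp covering 19.4 Mb, and replicate 2 had 121564 peaks with a median width of 200 bp covering 25.4 Mb. The longer deposited lists held 139425 and 182908 peaks, and the footprint lists 384018 and 505728 footprints. Replicate 2 had 1.38 times as many peaks as replicate 1, and the depths implied by the steps of the heights differed by 1.36 times in the same direction.

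Accessible regions were largely held in common. In replicate 1, 78968 peaks (89.5%, 95% interval 89.3 to 89.7) overlapped a peak of replicate 2, against 2.08% for randomly placed peaks, and in replicate 2, 79633 peaks (65.5%, 65.2 to 65.8) overlapped a peak of replicate 1, against 1.51%. With equal numbers of peaks, the 88222 strongest of each mouse, the shares were 79.8% and 80.2%. Merging gave 127470 regions, of which 76850 (60.3%, 21.4 Mb) held a peak of both mice. The share rose with height: in the lowest of 10 equal bins of height 59.8% of replicate 1 peaks and 15.8% of replicate 2 peaks were shared, and in the highest 99.9% and 99.0%. Of the peaks that were not shared, 49.3% in replicate 1 and 49.8% in replicate 2 lay in the longer list of the other mouse, and 70.5% and 62.4% held a position with a false discovery rate of 0.05 or less there. Peaks without any such position in the other mouse made up 3.09% of replicate 1 peaks and 13.0% of replicate 2 peaks.

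**Figure D1:**
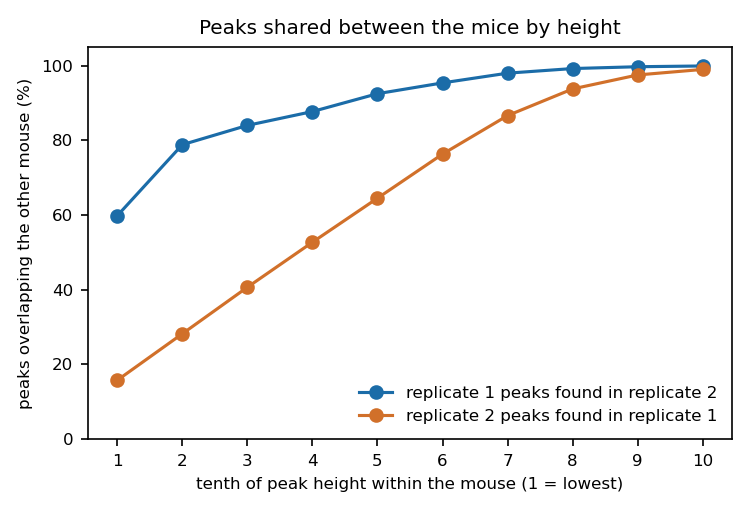
Share of each mouse's peaks (percent, y axis) that overlapped a peak of the other mouse, in 10 equal bins of peak height within the mouse (x axis, 1 is the lowest); points are single values per bin and mouse. The share rose from 59.8% to 99.9% in replicate 1 and from 15.8% to 99.0% in replicate 2.

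Heights of the same regions rose and fell together in the mice, with Pearson's r = 0.908 and Spearman's rho = 0.825 across the 127470 regions. Across the 76850 shared regions the median of the per-region ratios of replicate 1 to replicate 2 height was 1.31 (middle 50% of regions, 1.02 to 1.58). The median heights themselves were 1.05 and 0.890. This median ratio was 1.42 at the 22264 regions within 1000 bp of a TSS and 1.25 at the 54586 distal regions. It also differed with height, at 1.27 in the lowest of 10 equal bins of mean height and 1.55 in the highest. Regions near a TSS were taller, with a median height of 2.28 in replicate 1 against 0.889 at distal ones. The 2 kinds of region are compared at like height further below. Heights of single genes below therefore carry a difference between the mice that most genes share. A small SD of such heights is not a sign of close replication. The promoter of Myl4, at 9.46 in replicate 1 and 9.58 in replicate 2, ranked 2404 and 234 among the promoters of each mouse. Counted in steps of each mouse, the median ratio was 0.963. The region with the highest mean height lay on chromosome 17 from 39846781 to 39846920, with heights of 48.8 and 42.6. The nearest protein-coding TSS, that of Esp38, was 103669 bp away, and TSSs of other genes were not considered for this distance. No regions were removed here for repeated sequence, so whether repeats raised this height was not tested.

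Promoters were the class of DNA in which peaks were most concentrated. Peak centres lay in promoters in 26.5% ± 3.06 (SD, n = 2) of cases, 6.05 times the 4.37% of the genome that promoters cover. Introns held 39.1% ± 1.66 (SD, n = 2) of the centres, 0.972 times their share of the genome, and intergenic DNA 30.0% ± 1.59 (SD, n = 2), 0.572 times its share. Coding exons held 1.98% ± 0.202 (SD, n = 2) and 3' UTRs 1.42% ± 0.0114 (SD, n = 2), 1.77 and 1.23 times their shares. Distal regions made up 71% of the shared regions. Among the upper 50% of peaks by height the promoter share was 37.2%.

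Most protein-coding genes had an open promoter. A promoter peak was present for 13904 of 21851 genes in replicate 1 (63.6%, 95% interval 63.0 to 64.3) and for 14396 in replicate 2 (65.9%, 65.2 to 66.5). Both mice had it for 13760 genes (63.0%), replicate 1 alone for 144 and replicate 2 alone for 636, and 7311 genes had none. Of the 15 genes fixed in advance, all but Myh7 and Alb were open in both mice. The promoter of Gata4, a zinc finger factor of heart development on chromosome 14 from 63198922 to 63271692, had a height of 4.15 ± 1.5 (SD, n = 2), Hand2 4.39 ± 2.10 (SD, n = 2), Nkx2-5 2.75 ± 1.51 (SD, n = 2), Mef2c 2.12 ± 0.384 (SD, n = 2) and Tbx5 0.899 ± 0.199 (SD, n = 2). The Gata4 and Mef2c peaks lay inside their genes, in replicate 1 from 63245181 to 63245540 and from 83524461 to 83524900. Of the contractile genes, Actc1 (cardiac actin) reached 4.37 ± 2.57 (SD, n = 2), Ttn (titin) 2.99 ± 0.648 (SD, n = 2) and Tnnt2 (cardiac troponin T) 2.67 ± 0.995 (SD, n = 2). The paired myosin heavy chain genes on chromosome 14 differed: Myh6, the main adult ventricular form in mice, had a promoter peak of 4.12 ± 2.29 (SD, n = 2), and Myh7, the fetal ventricular form, from 54970684 to 54994626, had none in either mouse and 3 shared distal peaks. The natriuretic peptide genes Nppa and Nppb had heights of 1.59 ± 1.15 and 2.37 ± 1.19 (SD, n = 2), and Alb, the liver's albumin gene, had no promoter peak. The Nppb peaks, from 147985561 to 147985920 in replicate 1 and from 147985321 to 147985500 in replicate 2, did not overlap. The Nppb mean and SD therefore combine different peaks.

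Genes of the heart muscle's contraction and energy supply were open more often than other genes. Of the sarcomere genes, 18 of 20 had a promoter peak in both mice (90.0%, against 62.9% of other genes). The strongest were those of Myl4, an atrial myosin light chain gene, at 9.52 ± 0.0847 (SD, n = 2), and Tpm1 at 8.22 ± 1.76 (SD, n = 2). Tpm1, an alpha-tropomyosin gene on chromosome 9 from 67022590 to 67049406, begins at 67049406 on the minus strand. Its peak lay inside the gene, from 67043841 to 67043980 in replicate 1. The atrial light chain gene Myl7 and Myom2, which encodes an M-band protein, had no promoter peak. All 20 fatty acid oxidation genes were open, with Esrra, a nuclear receptor gene of energy metabolism, at 16.6 ± 8.39 (SD, n = 2), as were all 17 glycolysis genes, with Hk1 (hexokinase) at 10.2 ± 3.78 (SD, n = 2), and 19 of 20 oxidative phosphorylation genes, with Atp5b at 11.2 ± 2.42 (SD, n = 2) and the Atp5o entry used without a peak. That entry ran on chromosome 16 from 91684398 to 91926982. Only the first annotated entry of a symbol was taken, so whether Atp5o is open at another start was not tested. The Hk1 peak lay inside its gene, from 62340141 to 62340480 in replicate 1. Of the cardiac transcription factor genes, 21 of 22 were open, with Hey2 at 9.66 ± 3.28 (SD, n = 2) and Mef2a at 8.10 ± 2.23 (SD, n = 2), and Hand1, which marks early left ventricle, was the exception. Calcium handling and fetal and stress genes were open for 13 of 14 each, with Asph at 9.30 ± 4.43 (SD, n = 2) and Rcan1 at 9.46 ± 3.52 (SD, n = 2), and Sln (sarcolipin) and Myh7 without a peak. All 20 cell cycle genes and all 18 housekeeping genes were open, with Mcm5, a replication helicase gene, at 12.3 ± 3.69 (SD, n = 2) and the ribosomal gene Rplp0 at 14.9 ± 4.68 (SD, n = 2).

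Genes of vessels and connective tissue were open too. Of the endothelial genes, 18 of 19 had a promoter peak, among them Egfl7 at 2.55 ± 1.33 (SD, n = 2) and Esam at 2.43 ± 1.18 (SD, n = 2), and Plvap, a gene of fenestrated vessels, had none. Of the fibroblast genes, 17 of 18 were open, with the matrix genes Fn1 at 5.69 ± 2.00 (SD, n = 2) and Col1a1 at 3.19 ± 0.202 (SD, n = 2). Ion channel and gap junction genes (13 of 15, with the potassium channel gene Kcnj2 at 5.30 ± 2.37, SD, n = 2), pericyte and smooth muscle genes (13 of 15) and endocardial genes (9 of 10) were open about as often but did not pass, with adjusted p of 0.0725, 0.0725 and 0.107. Adjusted p for the lists called was 0.0170 for sarcomere, 0.0349 for fetal and stress and for calcium handling, 0.00171 for cardiac transcription factors and for glycolysis, 8.18e-04 for fatty acid oxidation and for cell cycle, 0.00431 for oxidative phosphorylation, 0.00675 for endothelial, 0.0108 for fibroblast and 0.00111 for housekeeping genes. Against random lists with the same promoter CpG content the calls of 4 of these 11 lists ended: the random median was 86.4% for cardiac transcription factors, 80.0% for oxidative phosphorylation, 95% for cell cycle and 94.4% for housekeeping genes. Under that matching the pericyte and smooth muscle list was called, at 86.7% against 53.3%. With replicate 2 alone the fetal and stress and the calcium handling calls ended at an unchanged 92.9%, and with replicate 1 alone the pericyte and smooth muscle list was called at 93.3%. The same 2 calls ended with a window of 2000 bp, with the longer peak lists and with a peak in either mouse, and among the upper 50% of peaks the fetal and stress and the endothelial calls ended at 71.4% and 73.7%. Ion channel genes were called, at 93.3%, with the 2000 bp window and with the longer lists, and pericyte and smooth muscle genes with these rules, at 100% and 93.3%, and with a peak in either mouse, at 93.3%.

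Genes of blood cells, liver and other organs were open less often than other genes. None of the 16 lymphocyte genes, Cd3e and Cd3d among them, had a promoter peak in both mice, which allows a share of up to 20.6% by the exact interval. Macrophage genes were open for 1 of 17, the lysozyme gene Lyz2 at 0.418 ± 0.0127 (SD, n = 2), and Csf1r and Ptprc had no promoter peak, although 16 shared distal peaks lay nearest to Ptprc. Hepatocyte genes were open for 2 of 19, germ line genes for 2 of 13, lung epithelium genes for 3 of 13, Schwann and autonomic nerve genes for 3 of 13 and erythroid genes for 5 of 15, and the beta-globin genes Hbb-bs and Hbb-bt had no promoter peak. Hox genes, which pattern the body axis, were open for 9 of 39, with Hoxa10 at 1.49 ± 0.0999 (SD, n = 2) and Hoxd13 without a peak, and olfactory receptor genes for 10 of 1092 (0.916%). Single genes of these lists had tall promoter peaks, such as the ciliary regulator gene Foxj1 at 6.37 ± 1.48 (SD, n = 2) and the germ cell gene Tex14 at 6.46 ± 2.01 (SD, n = 2). Any peak within 1000 bp of a TSS was counted, so a peak can belong to a neighbouring gene. The Tex14 peak of replicate 1 ended at 87404660, upstream of the gene's start at 87405065. Epicardial and mesothelial genes were open for 4 of 12, surface epithelium genes for 4 of 12, brain neuron genes for 7 of 18, skeletal muscle genes for 8 of 20 and adipocyte genes for 7 of 11, and none of these 5 lists passed, with adjusted p from 0.0513 to 1.

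For the 9 lists called less open, adjusted p was 1.73e-06 for lymphocyte, 9.60e-06 for macrophage, 1.86e-05 for hepatocyte, 0.00171 for germ line, 0.0114 for lung epithelium and for Schwann and autonomic nerve, 0.0401 for erythroid and 7.33e-06 for Hox genes, and lay below the smallest number the calculation could hold for olfactory receptors. Against lists with the same promoter CpG content the macrophage, hepatocyte and lung epithelium calls ended, with random medians of 23.5%, 31.6% and 38.5%, and the erythroid share of 33.3% lay above its random median of 26.7%. The same matching added calls of less open promoters for epicardial and mesothelial (33.3% against 58.3%), brain neuron (38.9% against 77.8%) and surface epithelium genes (33.3% against 66.7%). With replicate 2 alone the Schwann and autonomic nerve share was 38.5% and its call ended, and epicardial and mesothelial genes were called at 33.3%. With replicate 2 alone the brain neuron share was 61.1% and the olfactory receptor share 2.01%, and macrophage genes stood at 11.8% with either replicate alone. With replicate 1 alone skeletal muscle genes were called at 40%. The Schwann and autonomic nerve call also ended with a window of 2000 bp, the longer lists and a peak in either mouse, and the erythroid call, at 46.7%, with the 2000 bp window. Brain neuron and skeletal muscle genes were called with a window of 500 bp and among the upper 50% of peaks, and surface epithelium genes among the latter. The lists hold 10 to 39 genes apart from the olfactory receptors, and neighbouring genes such as those of the Hox clusters are not independent.

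**Figure D2:**
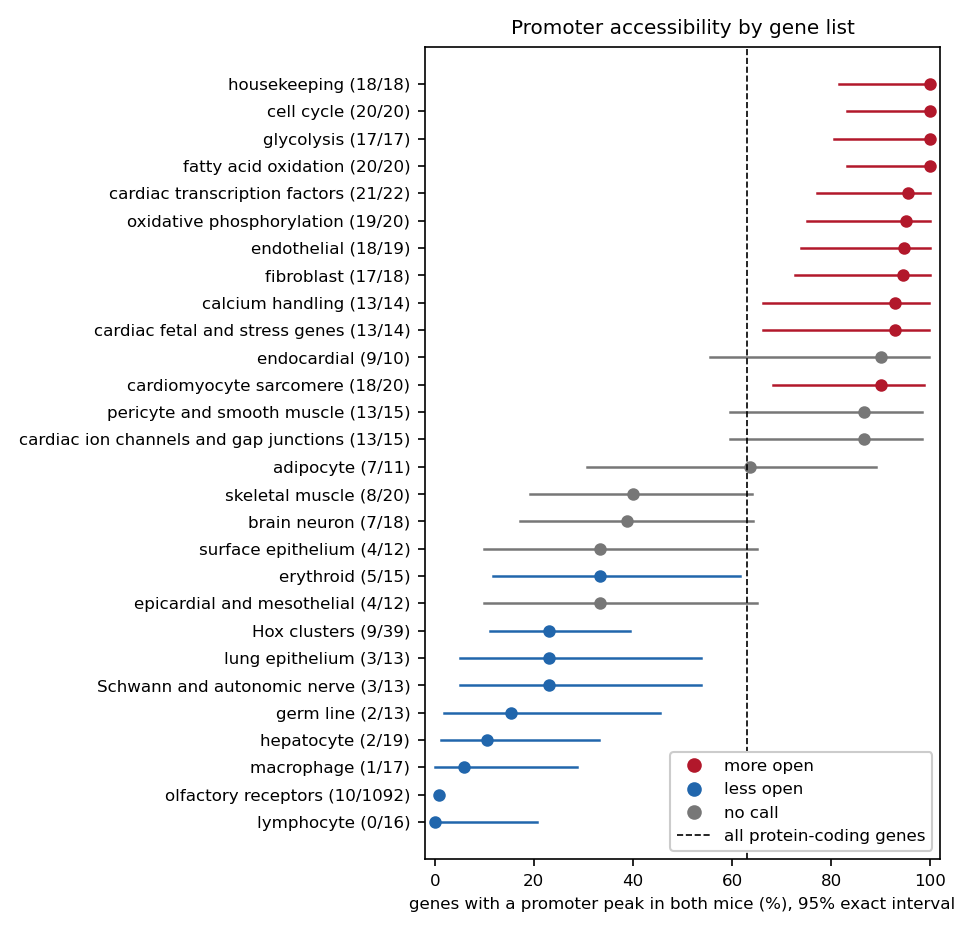
Share of the genes of each list with a promoter peak in both mice (percent, x axis), with lines for exact 95% intervals of counting error, and a dashed line at the 63.0% of all protein-coding genes. Of the 28 lists 11 were called more open and 9 less open, from 100% of fatty acid oxidation genes to 0.916% of olfactory receptor genes and 0 of 16 lymphocyte genes.

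Distal peaks were more numerous than in random lists around cardiac transcription factor, sarcomere, endothelial and fibroblast genes. Cardiac transcription factor genes had a median of 12.5 shared distal peaks per gene against 3.5 for random lists with the same territory, with 25 each at Prox1 and Tead1, 21 at Irx3 and 19 at Gata4. Sarcomere genes had 4 against 1, with 20 at Tpm1, 15 at Tnnt2 and 11 at Myom2, which had no promoter peak. Endothelial genes had 8 against 1, with 20 each at the vascular growth factor receptor gene Kdr and the cadherin gene Cdh5 and 14 at Flt1, and fibroblast genes had 9 against 3, with 24 at the collagen gene Col5a1, 12 at Fbln1 and 11 at Col1a1. These 4 lists passed the permutation test with adjusted p of 0.0028, and the central 95% of random medians was 1.5 to 7, 0 to 2, 0 to 4 and 1 to 6 in the same order. Calcium handling genes (8 against 2.5), ion channel genes (7 against 3), fetal and stress genes (3 against 1) and fatty acid oxidation genes (3 against 1) had adjusted p of 0.0714, and pericyte and smooth muscle genes (3 against 1) 0.0740. Endocardial genes (5 against 3.5) and epicardial and mesothelial genes (2 against 1.5) were not called, each with adjusted p of 1, and the remaining lists had adjusted p of 0.151 or more, and no list was called lower. Where the random range began at 0, as for lymphocyte, erythroid and olfactory receptor genes, no median could be called lower. The test therefore does not speak to fewer peaks in such lists. By the mean, olfactory receptors had 0.118 distal peaks per gene against 0.981 in random lists (permutation adjusted p 0.0056). The calcium handling, ion channel, fetal and stress, fatty acid oxidation and pericyte lists were each called under at least 1 alternative rule, as were glycolysis genes (2 against 0). With replicate 2 alone 8 lists were called higher and 1, the olfactory receptors, lower, and with replicate 1 alone 5 were called higher. With replicate 2 alone the medians of the lists called were larger, as were those of the random lists: 19.5 against 7.5 for cardiac transcription factors, 15 against 6 for fibroblast, 13 against 3 for endothelial and 6 against 2 for sarcomere genes. Of the lists not called from both mice, calcium handling had 17 against 6, ion channels 11 against 5, endocardial 9.5 against 7, glycolysis 5 against 1 and pericyte and smooth muscle 5 against 2 with replicate 2 alone. A peak was given to the nearest promoter, which need not be the gene it acts on.

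**Figure D3:**
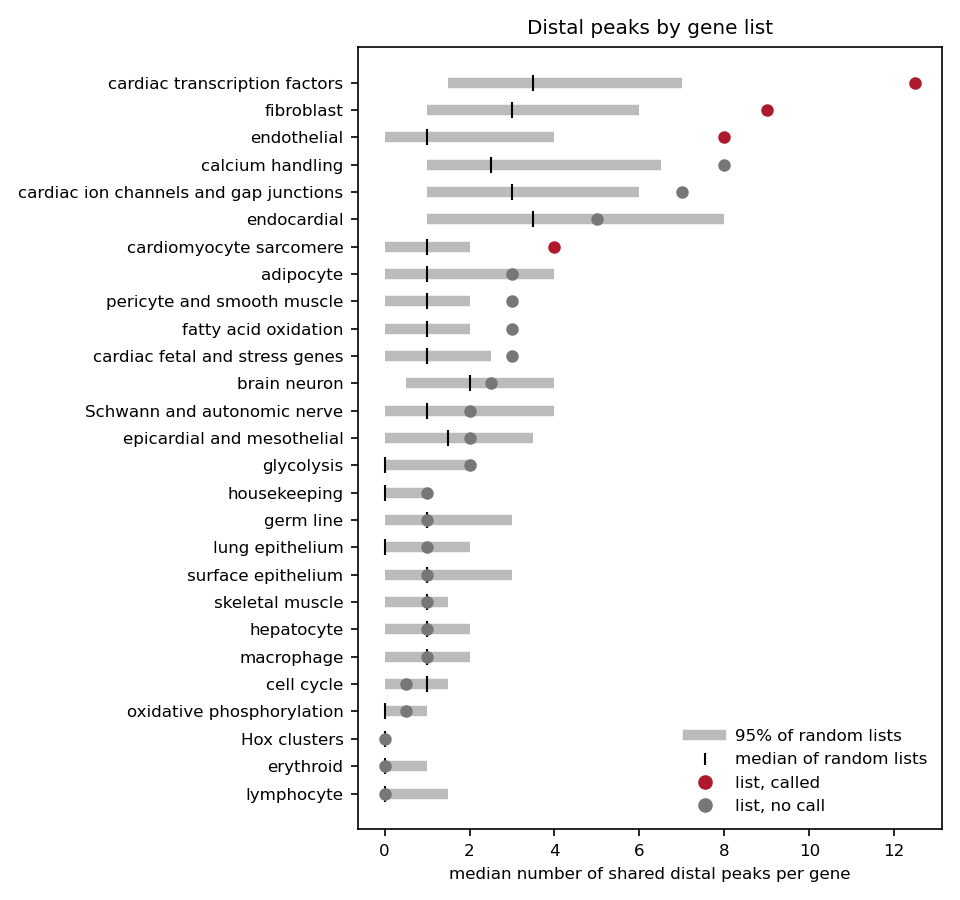
Median number of shared distal peaks per gene of each list other than olfactory receptors (x axis, peaks per gene; points), beside the median and central 95% of 10000 random lists matched on territory. The 4 lists called, cardiac transcription factors at 12.5, fibroblast at 9, endothelial at 8 and sarcomere at 4, lie beyond the random range.

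The gene with most shared distal peaks was Tns1, which encodes the focal adhesion protein tensin, on chromosome 1 from 73910231 to 74124449, with 72. It was followed by the repressor gene Bcor with 62, Zfp608 with 60, Auts2 with 55, Zmiz1 with 50, Rora with 49, Frmd4a with 45, Nfib and Zfp36l1 with 42 each and Adgrl2 with 41, a ranking that does not allow for territory. The densest window of 100 kb, on chromosome 11 from 98700001 to 98800000, held 36 shared peaks around Thra, a thyroid hormone receptor gene, and the clock gene Nr1d1, whose promoter reached 12.5 ± 6.28 (SD, n = 2). A window on chromosome 10 from 80100001 to 80200000 held 34, around the kinase gene Stk11 (promoter 14.9 ± 6.70, SD, n = 2) and Cirbp, and 1 on chromosome 1 from 73900001 to 74000000 held 33 within Tns1. A window on chromosome 11 from 69000001 to 69100000 held 29, with the clock gene Per1 at 14.3 ± 8.23 (SD, n = 2), and 1 on chromosome 18 from 35800001 to 35900000 held 28 around Cxxc5. The median of the 16836 windows with a shared peak was 3.

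By the same rule of 1 bp, smaller shares of footprints than of peaks overlapped between the mice. Peaks were far wider, at a median of 220 and 200 bp against 9 bp, so these shares do not compare how well each kind replicated. In replicate 1, 203802 footprints (53.1%) overlapped a footprint of replicate 2, and in replicate 2, 200574 (39.7%) overlapped 1 of replicate 1. Within the shared regions the shares were 62.2% and 55.4%, against 32.7% and 29.5% for footprints placed at random anywhere in these regions, 1.90 and 1.88 times as high. Random footprints were not kept in the region they came from. This control therefore does not separate protection at the same positions from regions that held many footprints in both mice. Footprints had a median width of 9 bp, and 67.6% of them in replicate 1 and 70.7% in replicate 2 lay in peaks of the same mouse. Of the peaks, 89.4% and 90.2% held a footprint.

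Sites of NRF1, CTCF, NFI and CREB were the most often protected. Sites of NRF1, an activator of genes for mitochondrial function, lay in footprints in 97.4% ± 0.172 (SD, n = 2) of 410 cases against 29.8% of shuffled sites, and sites of the insulator protein CTCF in 93.8% ± 4.20 (SD, n = 2) of 4095 against 24.9%. NFI sites were covered in 90.8% ± 6.22 (SD, n = 2) of 125 cases and CREB sites in 81.5% ± 2.82 (SD, n = 2) of 1002, 4.43 and 5.95 times their shuffled sites, and RFX and ETS sites 4.95 and 3.07 times. Sites and shuffled sites were not matched on location. Distal regions held 20.5% of ETS sites against 74.7% of shuffled ones, 15.9% against 44.5% for NRF1 and 89.7% against 33.3% for CTCF. In distal regions alone the ratios in replicates 1 and 2 were 1.99 and 1.79 for ETS, on 85 sites. They were 2.85 and 2.43 for NRF1, 5.44 and 4.41 for CREB and 5.20 and 4.50 for CTCF. Of the factors of muscle genes, SRF sites were covered in 24.4% ± 3.77 (SD, n = 2) against 11.5% and MEF2 sites in 18.5% ± 4.75 (SD, n = 2) against 12.7%. GATA sites, 14640 in number, were covered in 10.2% ± 0.932 (SD, n = 2) against 11.2% and were not called. NKX2 sites were covered in 13.1% ± 0.620 (SD, n = 2) against 15.4%, AP-1 sites in 10.9% ± 0.388 (SD, n = 2) against 14.3% and FOX sites in 5.55% ± 0.212 (SD, n = 2) against 10.6%, and these 3 were called less covered.

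Of the 27 sequences 16 were covered more than their shuffled sites in both mice by Fisher's exact test, 3 less and 7 neither, and REST had no control. The others called more covered were YY1 at 1.94 times, ESRR 1.87, SOX 1.76, NFY 1.59, the E-boxes CATCTG 1.44 and CAGCTG 1.09, SP/KLF 1.2 and TEAD 1.13. MEIS, HNF4, TBX, RUNX, PU.1 and HNF1, like GATA, were not called. When the whole site had to lie in a footprint, SOX and TEAD fell to 0.997 and 0.941 times their controls and the CAGCTG and NKX2 calls ended. With the mirrored position in the same region as control, SOX and TEAD stood at 0.932 and 0.936 times, and the MEF2 and ESRR calls ended. In distal regions alone the NFY call ended as its ratios fell to 1.08 and 1.05, and the NKX2 and YY1 calls ended with ratios of 0.939 and 0.820 and of 1.33 and 1.67, the latter on 29 of 381 sites. In the stronger regions by height the CAGCTG ratios were 0.910 and 0.913, against 1.5 and 1.36 in the weaker ones, and in the weaker ones the NFY ratios were 0.854 and 0.915, a split chosen after the values were seen. With replicate 2 alone GATA was called less covered, at 0.856 times its shuffled sites, and with replicate 1 alone its ratio was 0.982. With replicate 1 alone MEIS was called more covered, at 1.62 times (2.30 for whole sites, also called), and RUNX less, at 0.795 times. GATA was also called less covered by whole sites and by mirrored positions, and RUNX and PU.1 by mirrored positions. A consensus stands for a family of factors and does not tell which member was bound.

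**Figure D4:**
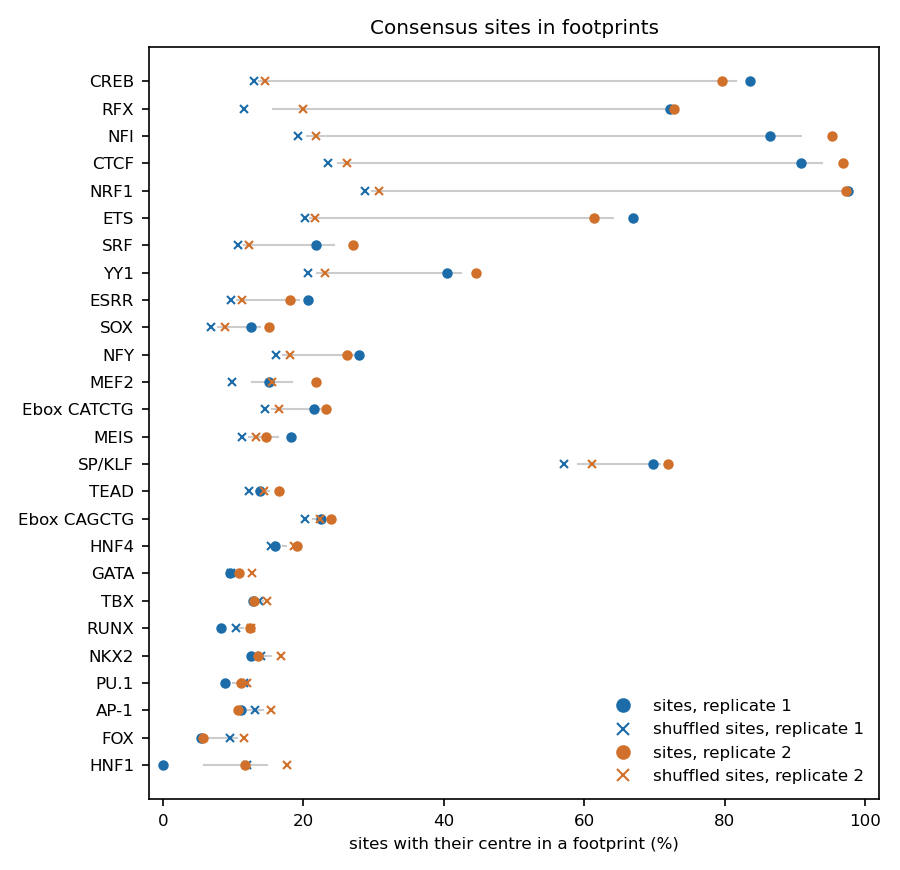
Share of sites of each consensus sequence lying in a footprint (percent, x axis), with dots for sites and crosses for shuffled sites, 1 per mouse. NRF1 sites were covered in 97.4% and CTCF sites in 93.8% on average, and GATA sites in 10.2% against 11.2% of shuffled sites.

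Genes of the X chromosome, of which males carry a single copy, were open less often and with lower peaks than autosomal genes. A promoter peak was present for 49.5% of the 948 X-linked genes and 66.0% of the 20720 autosomal genes as a mean of the mice, a difference of -16.5 points (-16.1 in replicate 1, -16.8 in replicate 2) with a permutation p of 1e-05, the smallest the resamples can give. The median height of X-linked promoter peaks was 2.26 in replicate 1 and 1.52 in replicate 2, against 4.40 and 3.11 for autosomal ones, 0.514 and 0.488 times as high with the same p. The X had 12.9 and 20.2 peaks per Mb and the autosomes 35.9 and 49.3. On the Y, 4 of 183 genes (2.19%) were open in both mice, and these were Kdm5d (0.714 and 1.06), Eif2s3y (1.70 and 1.74), Uty (1.66 and 1.40) and Ddx3y (2.10 and 1.44). A loss of reads from repeated Y genes was not tested, so the other Y genes need not be closed. Bcor, among the genes with most distal peaks, lies on the X.

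**Figure D5:**
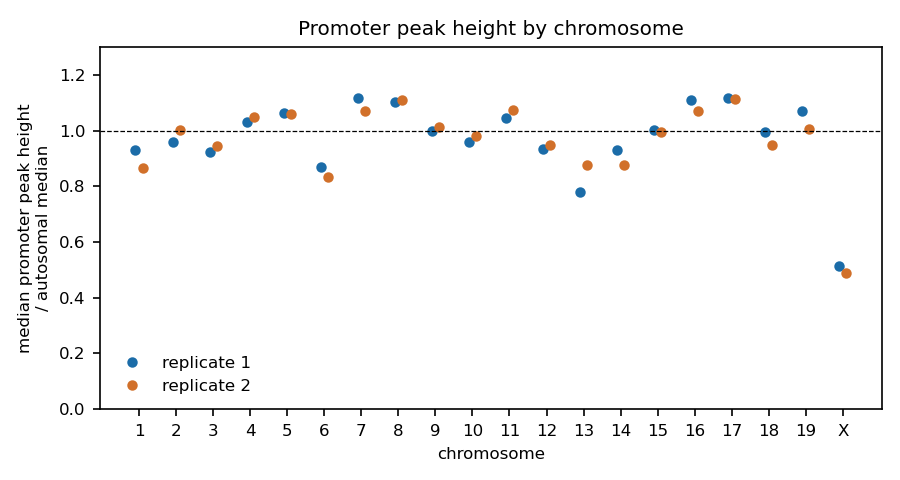
Median height of promoter peaks per chromosome (x axis) divided by the median over all autosomes (y axis, ratio), with 1 point per mouse and a dashed line at 1. The X, at 0.514 and 0.488, lies below every autosome in both mice, of which the lowest is at 0.778.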

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

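The alternatives added after seeing the data were the CpG-matched comparison of X heights, the correlation over regions with a peak in both mice, and the mean in place of the median for distal peaks. Under the other rules tried, 75.6% to 95.4% of replicate 1 peaks and 54.9% to 80.2% of replicate 2 peaks were shared, and the difference between the directions went away with equal numbers of peaks (79.8% and 80.2%). Between 12227 and 14614 genes had an open promoter. Lists with more distal peaks numbered 9 with a peak in either mouse, 7 for the upper 50% of peaks by height, 7 within 50 kb without matching, and 5 to 8 when a replicate was left out, and the 4 lists of the report kept their calls throughout. Lists with fewer numbered 1 with a peak in either mouse, 1 within 50 kb, 1 for the mean, and 0 to 1 when a replicate was left out. The upper 50% of peaks gave 37.2% promoter, 34.3% intron and 24.6% intergenic, and counting any overlap gave 37.3% intron. A reciprocal overlap of 50% gave 37.4% and 28.4% for shared footprints. Mirrored controls gave 6 sequences called less covered. The rank correlation was 0.825, and over regions with a peak in both mice r was 0.942. The X stood at 0.383 times the autosomes per Mb, against 0.75 by share of open promoters, and at 0.604 times by CpG-matched heights, against 0.501 without matching. Values that turned were the erythroid share, 33.3% and above its CpG-matched lists, SOX at 0.997 (whole site) and 0.932 (mirrored) and TEAD at 0.941 and 0.936. Except where the alternative itself narrows or widens what is counted, the cause was not tested.

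Of 550 values for single lists and sequences 469 kept direction and side of the threshold, 29 lost a call, 47 gained 1 and 5 turned. Matching on promoter CpG kept 12 of the 20 promoter calls, the fewest of the alternatives for that result. Footprints carry 1 constant value, so stricter footprints were not run, and shared peaks, shared footprints and the correlation need both mice and were not run with a replicate left out. Low peaks were shared least, 59.8% and 15.8% in the lowest of 10 bins of height, and whether depth is the cause was not tested.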

Other observations

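The tests of sequencing depth and both tests of binding sequences were chosen only after the result was seen, and for the X and the heights the unmatched ratios had been seen before the tests were set. No paired analysis was possible because the design has 1 group.

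X-linked promoter peaks were 0.514 and 0.488 times as high as autosomal ones. Lower CpG content of X promoters was not the whole cause, since against autosomal promoters with the same content the ratio was 0.608 (bootstrap 95% interval 0.516 to 0.721) in replicate 1 and 0.601 (0.503 to 0.693) in replicate 2, a mean of 0.604. Ordinary variation between chromosomes is argued against, since the lowest autosome stood at 0.778 times the autosomal median. A single X copy per male cell may account for lower peaks, but the matched ratios of 0.608 and 0.601 lay just above the range of 0.4 to 0.6 set for it. Their intervals lay on both sides of its edge and, in both mice, above 0.5. Only promoters with a peak entered these heights, 49.5% of X-linked and 66.0% of autosomal ones. Promoters too weak to be called are thus left out of the ratio, and the explanation remains open. No female sample was there to compare.

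Heights at shared regions were higher in replicate 1, with a median per-region ratio of 1.31, although replicate 2 had the greater implied depth. Counted in each mouse's own steps the median ratio was 0.963, so the direction rests on the authors' scaling. If heights are scaled to library depth, depth alone should give a ratio near 1, and no single factor can explain lists that differ from others of the same height. A uniform gain in the share of cuts inside peaks is argued against in the same way, and the ratio was higher near TSSs than at distal regions beyond the bootstrap spread in 8 of 10 equal bins of height, by 1.1 times or more in 5 of them, although in 0 was it above 1.1 beyond that spread. A candidate explanation is a difference in cell composition: 6 of 24 lists tested differed from height-matched random lists, with higher promoter ratios for sarcomere (1.85 against 1.40, permutation adjusted p 0.0028), endothelial (1.83 against 1.33, 0.0028), cardiac transcription factor (1.69 against 1.42, 0.00747), fetal and stress (1.71 against 1.35, 0.0098) and fatty acid oxidation genes (1.74 against 1.49, 0.0123) and a lower one for olfactory receptors (0.970 against 1.28, 0.0308). At distal regions sarcomere (1.48 against 1.27, permutation adjusted p 0.0135), endothelial (1.55 against 1.25, 0.0135), fetal and stress (1.48 against 1.26, 0.0202) and cardiac transcription factor genes (1.36 against 1.25, 0.0202) differed too and fatty acid oxidation genes did not (1.33 against 1.27, 0.535). These distal p-values came from 2000 random draws of single regions of like height, not of genes. The 116 sarcomere regions, for example, came from a list of 20 genes. Regions of 1 locus are not independent, so these p-values may be too small. Since pericyte and smooth muscle, fibroblast, endocardial and epicardial genes were not called in either direction, a shift between cell types, a difference in tissue taken and a quality difference between the libraries all stay open.

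Over all shared regions, sites of GATA, NKX2, AP-1 and FOX were not called as covered by footprints more than shuffled sites. Too few cuts in weak regions is argued against as the only cause, since in the stronger regions the highest of their ratios was 0.991. In the weaker ones GATA stood at 1.34 and 1.09 and AP-1 at 1.13 and 0.890. Dilution by promoters is argued against as the only cause as well, since in distal regions none of the 4 was covered more in both mice. The highest ratio there was 1.09 for GATA in replicate 1 against 0.894 in replicate 2, and the NKX2 call ended. Regions near a TSS were taller, so the stronger regions are richer in them. Strong distal regions were not tested alone, so both causes acting together stay open. No biological explanation was tested, and shuffling a consensus can change its CpG content, which was not matched.

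Values outside the comparisons, chosen after they were seen, include the largest difference between the mice, a region on chromosome X from 143482981 to 143483140. It lay 35530 bp from the nearest protein-coding TSS, that of Pak3, with heights of 5.28 in replicate 1 and 46.5 in replicate 2 (log2 ratio -3.14). Whether repeated sequence plays a part there was not tested. Of the 7311 genes without a promoter peak, 2700 (36.9%) had a shared distal peak and 117 (1.60%) had 10 or more, against 1239 of the 14540 genes with a promoter peak in either mouse (8.52%). The most were at Gm5148 with 35, Plcb4, a phospholipase gene, with 31 and Gm10260 with 29. Among genes open in 1 mouse only, 12 of the 144 of replicate 1 and 7 of the 636 of replicate 2 had a peak that overlapped a peak of the other mouse lying just outside the promoter window.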
